A study of Rattus norvegicus with 2 samples.

How the data were processed

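RNA sequencing was carried out on rat oligodendrocyte precursor cells (OPCs), the dividing glial cells that give rise to the myelin-forming oligodendrocytes. Per the labels' protocols, the cells came from the cortex of newborn pups by immunopanning, in which antibody-coated dishes hold back chosen cell types. They were electroporated with a scrambled small interfering RNA (siSCR) or with an siRNA against Hsc70 (siHsc70). Hsc70 is a constitutive member of the HSP70 chaperone family and is encoded by Hspa8. The siHsc70 sequence is TCATGACTGTCCTCATCAA (19 bases), and its position in the rat transcriptome was not analysed here. The cells were differentiated in medium with 60 nM of the thyroid hormone T3, and the series' design text gives day 2 of T3 and calls them immature oligodendrocytes. Total RNA was used for the libraries. There are 2 samples, 1 library per group.

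One table of the whole series was used. Its 6 columns of values hold, for each library, estimated counts, FPKM and TPM, and each column was tied to its sample by the siRNA in its name. The estimated counts are the authors' read counts per gene before normalisation, per the file headers. They need not be whole, and 26.55% of the siSCR values and 26.7% of the siHsc70 values are not. The deposited FPKM values are scaled for transcript length and for library size, per the file headers' name for them. The median ratio of estimated count to FPKM was 1.05 times as high in siSCR as in siHsc70, and so was the total count. The deposited TPM values sum to 999999.8 in siSCR and 999999.4 in siHsc70. The aligner, the quantification program, the annotation and the strand setting are not given in the sources used here. The submitters' processing notes name the mouse genome build mm39. The table nevertheless carries rat gene identifiers: 16783 of its 18049 gene IDs were found in a table of rat RefSeq genes (assembly GRCr8), 14969 of them with the same symbol. As the build is uncertain, no coordinates are given.

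Of the symbols in the table, 26 are whole numbers of the kind a spreadsheet program makes from names such as Sept4 or March1. They were replaced by the current RefSeq symbol of their gene ID, as were 697 names of the form LOC plus a number that now have a symbol. Hspa1b is 1 of these. The table holds no gene with a count of 0 in both libraries, and none of the mitochondrially encoded genes was found in it by the names searched. Those genes were not analysed here.

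Estimated counts were rounded to whole numbers and scaled to CPM (counts scaled to the same library total) with the TMM factors of edgeR 4.0.16 in R 4.3.3. The factors were 1.01 for siSCR and 0.992 for siHsc70. Total counts were 19085626 for siSCR and 18130817 for siHsc70, so that 3 counts, the limit that a count of 0 allows, correspond to 0.156 CPM and 0.167 CPM. Genes with a mean of at least 1 CPM over both libraries were called measured (13518 genes). Differences are log2(CPM + 1) in siHsc70 minus siSCR, with a pseudocount of 1, which understates the change of low genes. With 1 library per group no test between the groups is possible and no p-value is given. Genes are described by a rule of size, a difference of at least 1 on this scale, called here at least 2-fold. Folds of single genes are ratios of normalised counts without the pseudocount. They carry 95% exact (Clopper-Pearson) intervals from the reads of both libraries. These intervals and floors cover counting error only, not the spread between cultures, and PCR copies are not independent molecules.

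There were 34 gene lists (cell types, chaperones, lipid synthesis, stress and housekeeping pathways), and 30 had 5 or more measured members. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on 20 bins of mean expression, as a description of these 2 libraries. Its 95% interval is the order-statistic interval over the list's genes, which are not independent replicates. The gene lists, the rule of size, the rule for named genes and 8 processing alternatives were fixed before the data were examined. The rule named 12 genes in any case. It added for each list up to 2 higher and 2 lower members past the 2-fold rule, or the member furthest from 0 where none passed. It also added the 10 higher and 10 lower genes with the largest difference among genes with a mean of at least 10 CPM, leaving out rows deposited under a LOC name even where they now have a symbol. This gave 68 genes, of which 1 is not reported here. The alternatives were another pseudocount, other minimum means, other scalings, summed rows, another size of change and unmatched random lists. After the data had been seen, 3 more were added (the deposited TPM, the deposited FPKM, and pseudogene rows added to their gene), together with 4 gene lists.

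The procedure was tested on simulated data: Poisson counts drawn from the means and totals of the siSCR and siHsc70 libraries, over 13518 genes, with 200 genes changed. Of the genes changed 3-fold, 93.9% passed the 2-fold rule in the right direction, as did 95.9% of those changed 4-fold, 34.0% of those changed exactly 2-fold and 0% of those changed 1.5-fold. With no gene changed, over 13500 genes, counting error alone put 0 genes at least 2-fold higher and 0 at least 2-fold lower. Of 50 unchanged lists of 30 genes, 48 lay between the 2.5th and 97.5th percentiles, and 50 of 50 lists raised 1.5-fold lay above the 97.5th. The simulation held counting error only, with each gene drawn independently, and no spread between cultures. In the real libraries 11 of the 30 lists lay under the 2.5th percentile and 7 above the 97.5th, so a percentile past these limits was common. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.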

Results

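The transcriptome of rat OPCs differentiated for 2 days with 60 nM T3 was compared between cells that had received a scrambled siRNA (siSCR) and cells that had received an siRNA against Hsc70 (siHsc70). Each group was represented by 1 library, with a total estimated count of 19085626 for siSCR and 18130817 for siHsc70. A count above 0 was recorded for 17213 genes in siSCR and for 17291 genes in siHsc70, and 13518 genes were measured at a mean of at least 1 CPM. The 10 genes with the highest counts took 3.99% of the siSCR counts and 5.04% of the siHsc70 counts. The comparison asks which transcripts of differentiating oligodendrocytes depend on HSC70, in a study concerned with HSP70 chaperones, the transcription factor SOX10 and myelin formation. Because there were no replicates, the differences below describe these libraries, and whether they exceed the spread between cultures was not testable.

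The targeted gene was lower in the siHsc70 library, where Hspa8 (gene ID 24468) was at 507 CPM against 1399 CPM in siSCR, a 2.76-fold difference (95% counting interval 2.69 to 2.83). Reads of Hspa8 can be shared with a near-identical pseudogene row, Hspa8-ps25, which was 2.64-fold lower, and the sum of both rows was 2.71-fold lower (2.66 to 2.76). In the same library genes of newly formed and myelinating oligodendrocytes were mostly several-fold lower, Sox10 among them, and stress-inducible chaperone genes were higher. Over all measured genes, 695 were at least 2-fold lower (5.14%) and 310 were at least 2-fold higher (2.29%) in siHsc70, while the median gene differed by -0.0034 on the log2 scale. With the deposited TPM values the median gene shifted to -0.13 and the split was 810 lower and 207 higher genes.

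**Figure D1:**
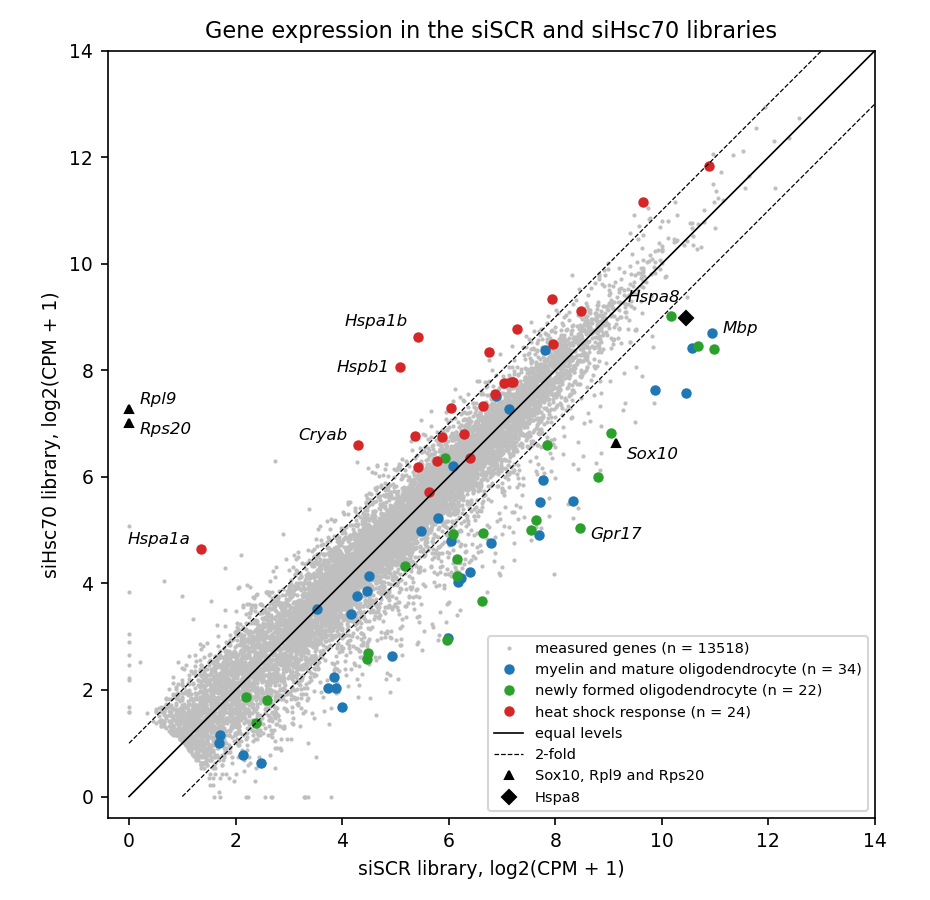
Expression of the 13518 measured genes in the siSCR library (x axis) and the siHsc70 library (y axis), both as log2(CPM + 1), with 1 library per group. Most myelin and newly formed oligodendrocyte genes lie below the lower 2-fold line, heat shock genes lie on or above the line of equal levels with 1 exception, and Hspa8 and Sox10 lie below the 2-fold line.

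Genes of the myelin sheath were lower as a group. Of 34 measured genes of myelin and mature oligodendrocytes, 21 were at least 2-fold lower and 0 were at least 2-fold higher in siHsc70. Mbp, encoding myelin basic protein, was 4.75-fold lower (4.64 to 4.87; 1968 against 414 CPM). Cnp, encoding a cytoplasmic protein of myelin, was 4.47-fold lower (4.35 to 4.59), and Mag, encoding an adhesion protein of the inner myelin layer, was 4.64-fold lower (4.31 to 5.01). Fa2h, whose product hydroxylates the fatty acids of myelin sphingolipids, was 9.10-fold lower (7.56 to 11.1). Mog, a late myelin gene, was low in both libraries, at 10.6 CPM in siSCR and 10.5 CPM in siHsc70, and its difference was within counting error. The list's median was -1.76 (95% interval -2.16 to -0.62), and 0 of 10000 matched random lists had a median as low.

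The genes of newly formed oligodendrocytes, the stage closest to the immature oligodendrocytes named in the design, were lower to a similar degree. Of 22 measured genes, 17 were at least 2-fold lower and 0 were at least 2-fold higher, with a median of -1.84 (-2.54 to -1.15), below all 10000 random lists. Gpr17, a receptor gene of committed precursors, was 11.1-fold lower (10.2 to 12.1; 352 against 31.8 CPM). Enpp6, an early marker of differentiation, was 9.28-fold lower (7.68 to 11.3; 61.9 against 6.67 CPM). Myrf, encoding a transcription factor that drives myelin genes, was 7.09-fold lower (6.66 to 7.55; 446 against 62.8 CPM).

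Sox10 (gene ID 29361) was itself 5.69-fold lower (5.41 to 5.98), at 563 CPM in siSCR and 98.9 CPM in siHsc70. Olig2, encoding another transcription factor of the lineage, was 1.43-fold lower (1.39 to 1.47; 540 against 378 CPM). Of 25 measured transcription factors and chromatin regulators of the lineage, 10 were at least 2-fold lower and 0 were at least 2-fold higher, with a median of -0.61 (-1.50 to -0.25). Of 16 measured genes reported elsewhere as SOX10 targets, 11 were at least 2-fold lower and 0 at least 2-fold higher. Their median of -1.36 lay below all 10000 random lists, although its interval over genes, -2.25 to 0.077, included 0, and 6 of the list's genes are also in the myelin list. Transcripts of the other proteins in the study's title were at similar levels: Hikeshi, which encodes a nuclear import carrier of HSP70, was at 41.3 CPM in siSCR and 44.3 CPM in siHsc70. Fbxw7, which encodes the substrate receptor of an SCF ubiquitin ligase, was at 26.5 and 25.2 CPM. Among 10 measured genes of that ligase and its regulators, 0 were at least 2-fold higher or lower, and the median was 0.025 with a mean of -0.024 (percentile 58.5), or -0.11 with the deposited TPM. The member furthest from 0 was the kinase gene Gsk3b, 1.38-fold lower (1.32 to 1.44).

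**Figure D2:**
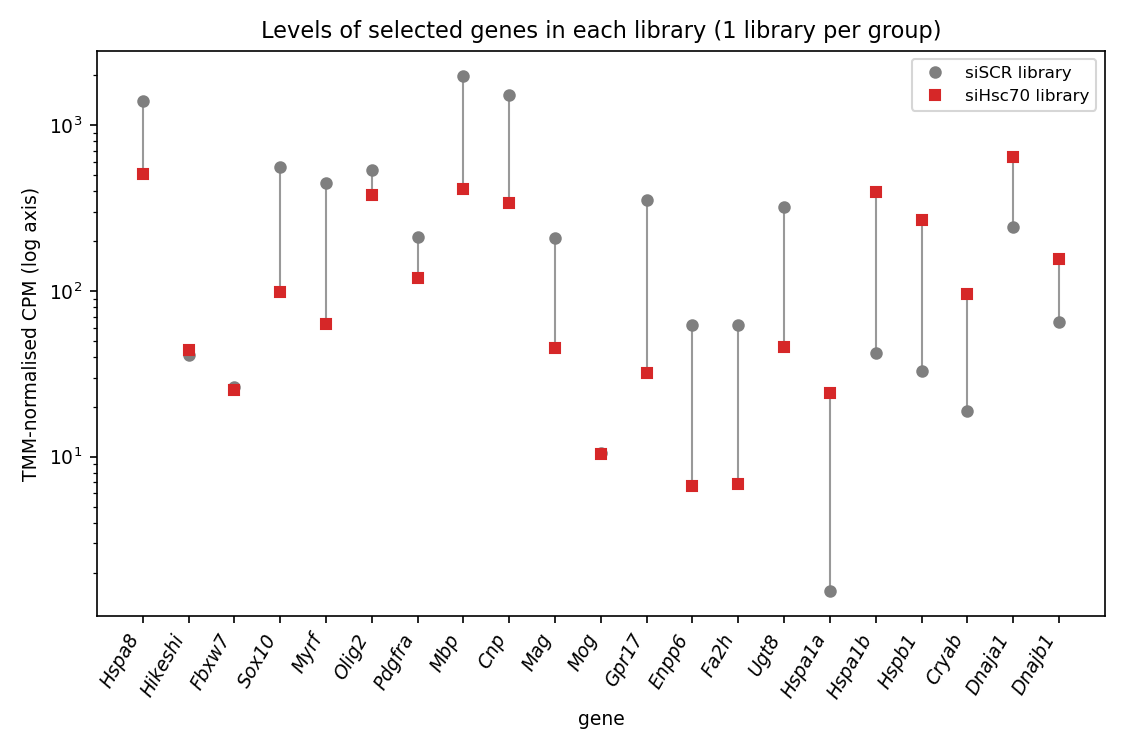
Levels of 21 genes in the siSCR library (circles) and the siHsc70 library (squares), as TMM-normalised CPM on a log axis, with 1 library per group. Sox10, Myrf and the myelin genes other than Mog are lower in siHsc70, Hikeshi, Fbxw7 and Mog nearly coincide, and Hspa1a, Hspa1b, Hspb1, Cryab, Dnaja1 and Dnajb1 are higher.

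Precursor-stage genes were also lower. Of 24 measured OPC genes, 9 were at least 2-fold lower and 0 were at least 2-fold higher, with a median of -0.77 (-1.60 to -0.23), below all 10000 random lists. Tnr, encoding the matrix protein tenascin-R, was 14.8-fold lower (13.2 to 16.6; 252 against 17.0 CPM), and Vcan, encoding the proteoglycan versican, was 6.08-fold lower (5.57 to 6.65). Pdgfra, encoding the growth factor receptor of OPCs, was 1.79-fold lower (1.69 to 1.88), and Cspg4, encoding the NG2 proteoglycan, was 2.14-fold lower (1.93 to 2.37). Cell cycle genes were lower as well: of 30 measured, 10 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.73 (-1.01 to -0.40). Cenpf and Top2a, both used in chromosome segregation, were 2.90-fold (2.36 to 3.60) and 2.31-fold (2.08 to 2.57) lower. Of 24 measured genes reported to restrain differentiation, most of them in Notch, BMP or WNT signalling, 3 were at least 2-fold lower and 0 higher, and the list's median of -0.11 was at percentile 17.2. Those lower included Bmp4, 8.26-fold lower (7.16 to 9.57), and the receptor gene Gpr37, 6.78-fold lower (4.86 to 9.68). The remaining one, Lingo1, was named after its values were seen, at 78.3 against 25.5 CPM. Of these 3, Gpr37 is also in the myelin list and Bmp4 in the newly formed oligodendrocyte list, and Gpr37 and Lingo1 belong to none of those signalling pathways.

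Stress-inducible chaperone genes were higher in siHsc70. Of 24 measured heat shock response genes, 10 were at least 2-fold higher and 0 were at least 2-fold lower, with a median of 0.81 (0.62 to 1.498), above all 10000 random lists. The inducible HSP70 genes Hspa1a and Hspa1b were 15.4-fold (10.7 to 23.2) and 9.37-fold (8.71 to 10.1) higher. These near-identical copies share reads, and together they were at 43.8 CPM in siSCR and 419 CPM in siHsc70, a 9.58-fold difference (8.92 to 10.3). The small heat shock protein genes Hspb1 and Cryab were 8.11-fold (7.47 to 8.83) and 5.10-fold (4.55 to 5.73) higher. Of 18 cochaperone genes of HSC70, 2 were at least 2-fold higher, Dnaja1 at 2.65-fold (2.56 to 2.74) and Dnajb1 at 2.41-fold (2.26 to 2.58). The list's median was 0.33 (0.13 to 0.65; percentile 99.9), or 0.19 with the deposited TPM. Dnaja1 and Dnajb1 are among 4 genes that this list shares with the heat shock list. Of 14 measured HSP70 family members, 4 were at least 2-fold higher and Hspa8 alone was at least 2-fold lower. The higher ones were Hspa1a, Hspa1b and, chosen after their values were seen, Hspa2 (38.0 against 102 CPM) and Hsph1 (107 against 324 CPM). That family's median of 0.52 lay at the 99.99th percentile with an interval, -0.18 to 1.59, that included 0. With the deposited TPM the family's median was 0.33.

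Lipid and cytoskeletal genes were lower in part. Among 24 cholesterol synthesis genes, 22 were lower by any amount but 0 passed the 2-fold rule, and the median was -0.35 (-0.52 to -0.17; 3 of 10000 random lists as low). The member furthest from 0, Acat2, encoding a thiolase, was 1.98-fold lower (1.82 to 2.15). Of 22 genes of fatty acid and sphingolipid synthesis, 3 were at least 2-fold lower, all of them also in the myelin list. They were Fa2h, Ugt8, whose product makes galactosylceramide and which was 6.96-fold lower (6.47 to 7.49), and Gal3st1, named after its values were seen, at 71.4 against 15.3 CPM. That list's median was -0.20 (-0.66 to 0.19), at the 1.49th percentile of matched lists. Of 27 cytoskeletal genes, 6 were at least 2-fold lower and 0 higher. Tppp and Tubb4a, a tubulin-polymerising protein and a tubulin abundant in oligodendrocytes, were 6.59-fold (6.04 to 7.21) and 5.51-fold (5.31 to 5.73) lower, and the list's median was -0.15 (-0.70 to 0.074), at the 0.85th percentile, with 3 genes shared with the myelin list. All 10 measured histone genes were lower in siHsc70 by less than 2-fold, with a median of -0.37 (-0.51 to -0.028; percentile 0.91). Hist2h2aa3 was the furthest from 0 and was 1.85-fold lower (1.36 to 2.55).

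The other stress, housekeeping and hormone response lists fixed beforehand had medians from -0.068 to 0.29. The unfolded protein response list had a median of 0.13 (percentile 88.8) and 0 of 25 genes past 2-fold, with Ppp1r15a furthest from 0 at 1.81-fold higher (1.73 to 1.88). The p53 and apoptosis list had a median of 0.13 (percentile 88.5), with Bbc3, a proapoptotic gene, 2.06-fold lower (1.83 to 2.33). The inflammation list had a median of 0.14 and a mean of -0.071 (percentile 84.0), with C3, a complement gene, 3.20-fold lower (2.40 to 4.31). With the deposited TPM the medians of these 3 lists were -0.013, -0.020 and -0.021. The immediate early list had a median of 0.14 (percentile 91.8), or 0.0022 with the deposited TPM. In that list Fosl1 and Ier3 were 2.14-fold (2.02 to 2.26) and 2.05-fold (1.95 to 2.16) higher, whereas Fos and Nr4a1 were 3.23-fold (2.78 to 3.76) and 2.97-fold (2.55 to 3.46) lower. The interferon list had a median of 0.29 (-0.055 to 0.76) at the 99.0th percentile, with Bst2, encoding an antiviral membrane protein, the 1 member of 20 past 2-fold at 7.40-fold higher (5.46 to 10.2). With a minimum mean of 5 CPM that median was 0.076. Proteasome, oxidative phosphorylation, and autophagy and lysosome genes had medians of 0.10 (percentile 93.1), 0.093 (94.9) and 0.19 (96.8), and with the deposited TPM these medians were -0.038, -0.047 and 0.046. The members furthest from 0 were Psmd11, 1.25-fold higher (1.20 to 1.31), Ndufa5, 1.46-fold higher (1.30 to 1.64), and Tfeb, encoding a regulator of lysosomal genes, 2.63-fold lower (2.23 to 3.12). The glycolysis list had a median of 0.25 (percentile 98.2), or 0.11 with the deposited TPM, with Gapdh 1.52-fold higher (1.51 to 1.54). Of 8 thyroid hormone response genes, Thra, a T3 receptor gene, and Hr, a T3-induced gene, were 2.51-fold (2.34 to 2.69) and 2.26-fold (2.14 to 2.39) lower, and the list's median was -0.068 (percentile 35.0).

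Markers of other cell types differed in both directions. Of 15 measured astrocyte genes, Aqp4 was 4.13-fold lower (3.69 to 4.64), Gfap was 2.12-fold lower (2.08 to 2.17; 1416 against 667 CPM) and Clu was 2.46-fold higher (2.31 to 2.62), with a list median of 0.098 (percentile 73.1) that was -0.025 with the deposited TPM. Of 16 neuronal genes, 4 were at least 2-fold lower: Dcx at 5.32-fold (4.35 to 6.57), Elavl3 at 2.90-fold (2.59 to 3.26) and, named after their values were seen, Gap43 and Syp. Nefh was 3.89-fold higher from 0.572 CPM (1.96 to 8.41). The neuronal median was 0.0089 (percentile 57.4), the mean was -0.18, and the median with the deposited TPM was -0.28. Of 10 fibroblast and mural genes, 3 were at least 2-fold higher: Col1a1 at 3.04-fold (2.74 to 3.39), Col6a1 at 2.28-fold (2.07 to 2.51) and, named after its values were seen, Postn. Cspg4, also in this list, was lower, and the median was 0.47 (-0.21 to 1.16; percentile 99.6). In the Schwann cell list, Dhh was 2.11-fold higher (1.88 to 2.38), while 3 genes were at least 2-fold lower, among them Mbp and, named after its values were seen, Ngfr. Mbp is among 2 genes that this list shares with the myelin list, so the list partly restates the lower myelin genes. The Schwann cell median of -0.39 (percentile 1.82) was 0.45 with a minimum mean of 5 CPM. Of 14 microglial genes, 1 was measured, Cd68, at 1.66 CPM in siSCR and 4.34 CPM in siHsc70. Of 10 endothelial genes 4 were measured, Flt1, Kdr, Esam and Egfl7, and of 2 erythroid genes 0 were. Cd68 and the endothelial genes were named after their values were seen.

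**Figure D3:**
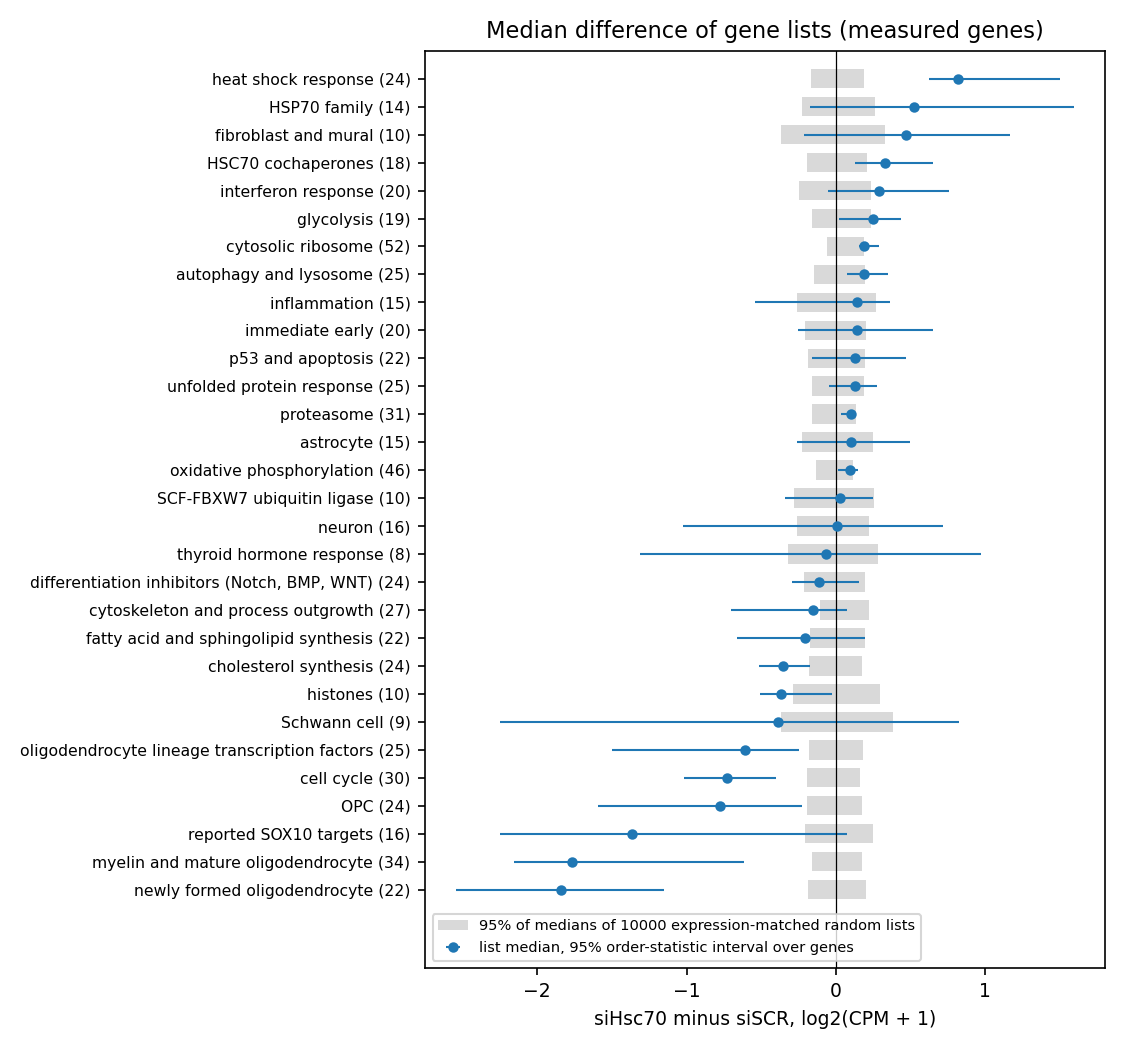
Median difference, siHsc70 minus siSCR in log2(CPM + 1), of the 30 gene lists with 5 or more measured genes (number in brackets). Points are list medians with 95% order-statistic intervals over genes, and grey bars hold 95% of the medians of 10000 expression-matched random lists. The heat shock list lies furthest to the right at 0.81 and the newly formed oligodendrocyte list furthest to the left at -1.84.

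Of the 10 lower genes with the largest difference at a mean of at least 10 CPM, 5 are those given above: Tnr, Gpr17, Enpp6, Fa2h and Bmp4. The other 5 were the growth factor gene Igf2, 12.6-fold lower (8.92 to 18.5), the semaphorin gene Sema5a, 8.82-fold lower (8.14 to 9.58), the plexin gene Plxnb3, 8.30-fold lower (7.69 to 8.96), Rassf10, 9.98-fold lower (7.499 to 13.5), and the kinase gene Prkcq, 8.46-fold lower (7.04 to 10.2). Among the 10 higher genes were Hspa1a, Hspb1, Cryab and Bst2. Hspa1b differed by more than Hspb1 but was deposited under a LOC name, which the rule for these 10 leaves out. Tprkb was 6.74-fold higher (5.16 to 8.94), the tropomyosin gene Tpm2 4.56-fold higher (3.75 to 5.60) and the thrombomodulin gene Thbd 4.36-fold higher (3.70 to 5.15). The remaining 3 were ribosomal protein genes with near-identical copies: Rpl9, Rps20 and Rpl37. Rpl9 and Rps20 had estimated counts of 0.33 and 0.01 in siSCR against 2765 and 2299 in siHsc70, and with their pseudogene rows added the ratios of siHsc70 to siSCR were 1.14 (1.10 to 1.18) and 1.34 (1.29 to 1.39). Rpl37 was 13.5-fold higher (11.1 to 16.6), and 13.0-fold with the rows named as its pseudogenes, from 6.08 CPM in siSCR. Any copies under other names were not added, so this fold is uncertain. The list of 52 cytosolic ribosome genes had a median of 0.19 (percentile 97.75), or 0.046 with the deposited TPM, and 4 members were at least 2-fold higher. They were Rps20, Rpl37 and, named after their values were seen, Rps13 and Rpl38, whose ratios with pseudogene rows added were 1.08 (1.03 to 1.13) and 1.37 (1.26 to 1.48).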

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

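The 3 alternatives added (the deposited TPM, the deposited FPKM and pseudogene rows added to their gene) were chosen after the data had been seen. The difference of Hspa8, -1.46 in the main analysis, was -1.40 under upper-quartile scaling and -1.60 with the deposited TPM. The number of genes at least 2-fold higher was 518 with a pseudocount of 0.1 and 203 with the deposited FPKM, against 310. With a 1.5-fold rule there were 1304 higher and 1626 lower genes. The medians of the oxidative phosphorylation and proteasome lists changed sign with the deposited TPM, to -0.047 and -0.038, where the median of all genes was itself -0.13. Under every setting run, the medians of the myelin (-2.01 to -1.04), newly formed oligodendrocyte (-2.02 to -1.70) and OPC (-0.96 to -0.71) lists stayed below 0 and that of the heat shock list (0.66 to 0.88) stayed above 0. Against random lists not matched on expression, the fatty acid and cytoskeletal lists moved to percentiles 2.91 and 6.675, from 1.49 and 0.85. Of the values of single genes and of other lists, 748 stayed within the 95% interval of the main value (for percentiles, on the same side of the limits), 88 moved beyond it, and the 2 given above changed sign although their interval excluded 0. The cause of these shifts was not tested. Many of the 748 could not have moved, because the filters on low values and the summing of rows leave most single genes' values unchanged. The count therefore overstates stability. No paired analysis was possible because each group holds 1 library, which also leaves no replicate to leave out. Depth limits the precision of low genes: for Nefh the counting interval of the ratio reached from 1.96 to 8.41.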

Other observations

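The tests of explanations in this part, the 4 gene lists named first and the genes named from them were chosen after the values had been seen, while the other lists and 3 of the 5 scalings compared were planned. Ranks of these 4 lists among random lists, which were not chosen by value, are therefore descriptions and no independent support. Genes of the NRF2 antioxidant response were higher in the siHsc70 library in 29 of 29 measured cases, 6 of them at least 2-fold. The list's median was 0.87 (95% interval over genes 0.70 to 0.95), above all 10000 expression-matched random lists. Nqo1, a quinone reductase gene, was 2.47-fold higher (counting interval 2.43 to 2.52), Hmox1, encoding heme oxygenase, 2.12-fold (2.09 to 2.14), and Slc7a11, encoding the cystine transporter, 2.26-fold (2.21 to 2.30). The ferritin heavy chain gene Fth1, the gene with the most counts in siHsc70, was at 3944 CPM in siSCR and 7843 CPM in siHsc70. A row named as its pseudogene is also in the table, so that its level is uncertain. A list of actin-binding and mesenchymal genes was higher in 24 of 24 cases, 8 of them at least 2-fold, with a median of 0.82 (0.43 to 1.04). The list was drawn up after Tpm2, 1 of its members, had been seen among the 10 higher genes, and fibroblast genes such as Col1a1 (3.04-fold) and Col6a1 (2.28-fold) were higher in the same library. Its members included Lgals1, encoding galectin-1, at 2.52-fold (2.41 to 2.65), and Vim, encoding vimentin, at 5967 CPM in siHsc70 against 3468 CPM in siSCR.

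Guidance and septin genes were lower in part. Of 48 semaphorin, plexin, neuropilin and ephrin genes, 8 were at least 2-fold lower and 0 at least 2-fold higher. Their median was -0.17 (-0.31 to 0.15; percentile 1.04), with an interval that included 0. Sema5a and Plxnb3, already seen among the 10 lower genes, are counted in the 8, so the count and the percentile partly restate that observation. Ephb1, an ephrin receptor gene, was 6.99-fold lower (5.9988 to 8.19). The septins, cytoskeletal GTPases of which several are found in myelin, are among the genes whose symbols the table holds as spreadsheet dates. Of 10 measured, 3 were at least 2-fold lower: Septin5 at 3.39-fold (3.17 to 3.62), Septin3 at 3.48-fold (2.81 to 4.33) and Septin4 at 2.42-fold (2.18 to 2.70). The septin median was -0.42 (-1.645 to 0.21; percentile 0.36).

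Under 5 scalings the myelin and newly formed oligodendrocyte medians came no closer to 0 than -1.70. These scalings moved the median of all genes only between -0.13 and 0.059. They could hardly have brought the 2 list medians near 0, so this outcome gives little support. A loss of lineage cells of every stage, as the whole cause, would lower Olig1 and Olig2, made throughout the lineage, as far as these lists. Olig1 was instead higher, at 1359 CPM in siHsc70 against 1207 CPM in siSCR. The lowest counting bound of the pair, that of Olig2, was -0.56. It lay well above the upper bound of the newly formed oligodendrocyte median, -1.15, and narrowly above that of the myelin median, -0.62. Sox10, another transcription factor gene of the lineage, was at -2.50, lower than both medians. Loss alone, equal at every stage, would lower Sox10, Olig1 and Olig2 to a like degree, which was not seen. Whether cells outside the lineage gave part of the Olig1 and Olig2 reads was not examined. Loss as the whole cause is therefore not settled by these genes. Cells held at the precursor stage with precursor genes kept or raised would put the OPC list at or above 0, whereas its median was -0.77 (-1.60 to -0.23).

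Among markers of other cells, the astrocyte median was 0.098 (-0.26 to 0.50) and the fibroblast and mural median 0.47 (-0.21 to 1.16), both with intervals that include 0. Astrocyte genes went either way, with Gfap 2.12-fold lower and Clu 2.46-fold higher. Of 10 fibroblast and mural genes, 8 were higher by any amount, among them Col1a1 at 3.04-fold and Col6a1 at 2.28-fold. The 2 lower ones were Cspg4, at 2.14-fold, and Col3a1, at 2.29 CPM in siSCR and 1.835 CPM in siHsc70. Cspg4 is also in the OPC list, so the fibroblast and mural median and its interval rest partly on an OPC gene. The fibroblast and mural median lay at percentile 99.6 of matched random lists. A loss of lineage cells or a larger share of other cells, as all or part of the cause, stays open. So do lower transcription in the cells still present, an off-target effect of the siRNA and a difference between the cultures unrelated to it. Beyond the values given above for Olig1, Olig2 and Sox10, none of these was tested.

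The higher heat shock genes may partly reflect a broad stress response to delivery of the siRNA, although both cultures were electroporated with one. The medians of 5 other stress lists (unfolded protein response, p53, immediate early, interferon, inflammation) reached at most 0.29, but the upper bounds of the interferon and immediate early medians, 0.76 and 0.65, exceed the lower bound of the heat shock median, 0.62, so this stays open, and the NRF2 genes were higher too. Reads of the HSP70 copies assigned to one another are argued against only for the rest of the list: without HSP70 family members the remaining 20 heat shock genes had a median of 0.73 (0.62 to 1.40). For Hspa1a and Hspa1b themselves only the sum of both was examined, so reads shared with other HSP70 genes stay open. A response to the lower level of HSC70 itself, the difference the design names, was not tested.

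The near-zero estimates of Rps20 and Rpl9 in siSCR are consistent with reads split between near-identical copies. The rows Rps20-ps11 and Rpl9-ps31 were at 259 and 319 CPM in siSCR and at 220 and 210 CPM in siHsc70. With all pseudogene rows added, the larger of the 2 differences was 0.42 on the log2 scale. No biological explanation was tested. Rpl37 did not follow: the summed rows still differed by 3.50. Only rows named as numbered pseudogenes were added, so reads placed on copies under other names stay possible for Rpl37.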
